A study of Homo sapiens with 4 samples.

How the data were processed

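RNA of 4 cultured lines was measured on a 1-colour circRNA microarray, with 1 array per line. Per the labels' protocols, total RNA was digested with RNase R, an exonuclease that degrades linear RNA, and the remaining RNA was amplified by random priming into Cy3-labelled cRNA. Linear mRNA values therefore describe what was left after digestion. The source name in the labels calls the material frozen breast tissue, whereas the cell line and culture labels describe cultured cells. The groups were taken from the cell line labels. Per the file headers, all 4 arrays lay on 1 slide, so slide could not differ between lines.

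The deposited scanner files hold linear intensity per spot, per the file headers, with Agilent's background-subtracted processed signal, the median signal, the local background and quality flags. Agilent Feature Extraction 11.0.1.1 and limma, with no version, are named in the submitters' processing notes. Genome positions of the probes were not used here. The deposited normalized table holds log2 values for 12545 circRNA probes, all of them well above background on at least 2 arrays, while the other 1072 were above on 0 or 1. Its column medians were 7.80 for the parental line, 7.81 for BM6, 7.79 for LM2 and 7.80 for 1833, with a common maximum of 16.7. Each column correlated with the quantile-normalized log2 median signal of the same array at 0.9985 or more, with a slope of 1.08, so its scale is log2 without gene centring, but the exact method stays unknown.

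For the main values, log2 of the processed signal was taken and each array's 75th percentile over circRNA probes was subtracted. Probes with 10 spots were averaged on the log2 scale after leaving out outlier spots. Scaled intensities are these values returned to the mean 75th percentile of the arrays. CircRNA probes were compared where they were well above background on both arrays and carried no outlier or saturation flag; 1 circRNA spot was an outlier and none was saturated. A probe with 10 spots counted as above background with 6 or more spots above it, a rule set after the files were seen. A probe above background on 1 of the 2 arrays has only a bound: the brighter value was set against the higher of the lowest signal well above background and the dim probe's own. With 1 array per line no test between lines was possible, and circRNAs were counted at fixed folds of 2 and 4.

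Technical noise was taken from the repeated spots, whose median SD within an array was 0.056 in the parental line, 0.058 in BM6, 0.058 in LM2 and 0.052 in 1833 on the log2 scale. Noise by level, in 8 bins, ran from 0.23 for the dimmest to 0.032 for the brightest. It covers neither culture, RNA preparation nor labelling. From it, 100 pairs of unchanged arrays were simulated per comparison, and they gave a mean of 0.91 probes past 2-fold for BM6, 0.41 for LM2 and 1.07 for 1833. The count was tested on simulated data with 200 changed probes. A true 4-fold difference was called for 100% of them in each comparison, a true 2-fold difference for 54% in BM6, 49% in LM2 and 55.5% in 1833, and a true 1.5-fold difference for 1% or less. The 2-fold rates follow by construction, since such a difference lies on the threshold. With spot noise alone, the rates do not tell how well differences between separate preparations are recovered.

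The choice of comparisons, fold, gene lists, alternatives and naming rule was made before the data were examined. The naming rule took the 12 highest and 12 lowest circRNAs per comparison among probes brighter than the median of measured probes. Because the files and the reference pair no probe ID with a circRNA or gene name, 2 IDs per direction are printed, and host gene lists, chromosomes, circRNA classes and known circRNAs were not analysed here. The 70 mRNA probes carry RefSeq accessions, and all 70 were matched without version to symbols in the RefSeq table of assembly GRCh38.p14, whose coordinates were not used. Naming mRNAs at least 1.5-fold apart, and the members of the fixed lists, was decided after the files were seen; 1 such mRNA is counted but not reported here by name or drawn. The mRNA median was placed among 10000 random circRNA lists matched in 20 bins of level, as a description of these arrays.

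The alternatives were quantile normalization, scaling to the median, cyclic loess, normexp background correction with an offset of 50, the deposited log2 values, no filter on dim probes, brighter probes alone and a 1.5-fold threshold. Normexp was planned on the mean signal; the median signal was used in its place with the background median. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Control probes were left out of all counts.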

Results

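Circular RNAs (circRNAs), which arise when a splice donor is joined to an upstream acceptor, were measured in 4 cultured human breast cancer lines. These were the parental line MDA-MB-231 and 3 sublines of metastatic origin. BM6 is labelled as a brain metastasis line, LM2 as a lung metastasis line and 1833 as a bone metastasis line. The design asks which circRNAs differ in metastatic sublines from the line of origin. Each line was hybridised to 1 array, so no value has a replicate, no p-value is given, and the number of arrays limits the precision. The array held 13617 circRNA probes with 1 spot each and 70 linear mRNA probes with 10 spots each. The files name circRNA probes by the designer's IDs without host genes or genomic positions, so these probes are given by ID. Of the circRNA probes, 12554 (92.2%) were well above background in the parental line, 12434 (91.3%) in BM6, 12120 (89.0%) in LM2 and 12442 (91.4%) in 1833. LM2 was the dimmest array, with a median circRNA intensity of 108, against 179 in the parental line, 184 in BM6 and 196 in 1833. Over the 11920 probes measured on all 4 arrays, Pearson's r of log2 intensity across probes, which are not independent replicates, lay between 0.957 for BM6 with 1833 and 0.966 for the parental line with BM6.

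The first comparison was between BM6 and the parental line. The circRNA ASCRP3003814 was 39.9-fold higher in BM6, with a scaled intensity of 1375 against 34.4 in the parental line, and ASCRP3009212 was 37.7-fold higher. In the other direction, ASCRP3001333 was 11.4-fold lower, at 220 against 2502, and ASCRP3006981 was 7.53-fold lower. On the log2 scale ASCRP3003814 differed by 5.32, by 4.05 under normexp and by 4.54 in the deposited values, ASCRP3009212 by 5.24 and by 4.22 under normexp, and ASCRP3006981 by -2.91 and by -2.33 under normexp. Among 12282 probes measured on both arrays, 585 were at least 2-fold higher in BM6 and 533 at least 2-fold lower, together 9.10%. At 4-fold the counts were 80 and 45. Of 151 probes well above background in BM6 but not in the parental line, 65 were at least 2-fold higher by their bound, and of 271 seen in the parental line but not in BM6, 45 were at least 2-fold lower. The scaled detection floor of BM6 was 1.26 times that of the parental line, which favours larger bounds on the higher side than on the lower side. Of the 50 linear mRNAs measured on both arrays, 7 were at least 1.5-fold higher and 15 at least 1.5-fold lower. *ODC1*, encoding ornithine decarboxylase of polyamine synthesis, was higher by 1.62 ± 0.23 on the log2 scale, where the error here and for other mRNAs is the SD over repeated spots and covers technical noise within arrays only. *LOX*, encoding the collagen cross-linking enzyme lysyl oxidase, was higher by 0.95 ± 0.11 and *RPAP3*, encoding a chaperone cofactor, by 0.92 ± 0.08. The DNA repair gene *SMC6* differed by 0.60 ± 0.09 and *GAPDH* by 0.59 ± 0.06. *NOC3L*, which encodes a nucleolar protein, had a log2 difference of -1.58 ± 0.27. The difference was -1.40 ± 0.04 for *MOCOS*, the molybdenum cofactor sulfurase, and -1.20 ± 0.13 for *ZAP70*, a kinase of T cell receptor signalling. *SPDL1*, a mitotic spindle gene, differed by -1.14 ± 0.07, *ACTB* (beta-actin) by -0.91 ± 0.04 and the metadherin gene *MTDH* by -0.70 ± 0.08. The mRNA *CENPQ*, of the kinetochore, was not well above background in BM6 and was at least 2-fold lower there, while *LMO2*, seen only in BM6 of this pair, was at least 1.71-fold higher. The median of the 49 mRNAs measured on all 4 arrays was -0.26, at percentile 0.26 of 10000 random lists of circRNA probes matched on level, whose central 95% ran from -0.17 to 0.19. The SD of the circRNA differences was 0.62, which was 4.75 times that of simulated unchanged arrays carrying only spot noise. Normexp background correction gave 243 higher and 231 lower circRNA probes and the deposited normalized values gave 322 and 297. Under normexp 4 of the 22 mRNAs stayed past 1.5-fold, and the difference of *ODC1* was 0.42, of *LOX* 0.42, of *SMC6* 0.31 and of *GAPDH* 0.56, with *GAPDH* at 0.57 after quantile normalization. It was -0.58 for *NOC3L*, -0.46 for *ZAP70*, -0.75 for *SPDL1* and -0.43 for *MTDH*.

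The second comparison was between LM2 and the parental line. ASCRP3008906 was 65.8-fold higher in LM2, at a scaled intensity of 2111 against 32.1, and ASCRP3003805 was 35.3-fold higher. On the log2 scale ASCRP3008906 differed by 6.04, by 4.67 under normexp and by 5.29 in the deposited values, and ASCRP3003805 by 5.14 and by 4.17 under normexp. ASCRP3005803, a bright probe at 26149 in the parental line, was 34.4-fold lower in LM2 at 759, and ASCRP3011481 was 29.8-fold lower. Among 12040 probes measured on both arrays, 821 were at least 2-fold higher and 497 at least 2-fold lower, together 10.9%. At 4-fold the order turned, with 50 higher and 68 lower. Of 513 probes seen in the parental line but not in LM2, 41 were at least 2-fold lower by their bound. The 79 seen in LM2 but not in the parental line give no such count, since the scaled detection floor of LM2 was 2.18 times that of the parental line and puts any probe set against the parental floor past 2-fold. A probe whose parental value lay between these floors entered the 12040 only if higher in LM2, which favours higher counts. The median circRNA difference was 0.12 on the log2 scale, so the mRNA differences of LM2 are given relative to that median. On this basis 8 of 52 measured mRNAs were at least 1.5-fold higher and 8 at least 1.5-fold lower, against 11 and 4 without the adjustment, as BM6 and 1833 are given. *SAA4*, of the serum amyloid family, differed by 1.17 ± 0.49, the chromatin remodeller gene *SMARCAD1* by 0.91 ± 0.40 and *GAPDH* by 0.83 ± 0.06. *DTL*, encoding a ubiquitin ligase adaptor, differed by 0.75 ± 0.31, *ODC1* by 0.71 ± 0.34 and *MTDH* by 0.70 ± 0.08. The recombination gene *RAD54B* differed by 0.60 ± 0.11. *GRM4*, a glutamate receptor gene, was not well above background in the parental line. Before adjustment for the circRNA median it was at least 3.56-fold higher in LM2, of which 2.18-fold follows from the gap between the floors alone. On the lower side were *MOCOS* at -1.21 ± 0.06, *SPDL1* at -0.85 ± 0.09, the DNA primase gene *PRIM1* at -0.81 ± 0.05 and *LOX* at -0.71 ± 0.20. The alternatives that follow are each relative to their own circRNA median, which was 0.24 under normexp. Of the 15 mRNAs past 1.5-fold before adjustment, 12 were past it relative to the median, 8 after quantile normalization, 7 after cyclic loess and 3 under normexp. Under normexp *LOX* was at 0.09, within the spot SD of 0.20 of its main value, *SPDL1* at -0.46, *PRIM1* at -0.63, *SAA4* at 0.55, *MTDH* at 0.50 and *RAD54B* at 0.46. After quantile normalization and cyclic loess *DTL* was at 0.44 and 0.39, *ODC1* at 0.39 and 0.47, *SMARCAD1* at 0.60 and 0.52, *RAD54B* at 0.50 and 0.47 and *SAA4* at 0.83 and 0.70. *DTL* was at 0.50, *ODC1* at 0.47 and *SMARCAD1* at 0.52 under normexp. The median of the 49 mRNAs measured on all 4 arrays lay at percentile 52.5 of the random circRNA lists. The SD of the circRNA differences was 0.66, 5.46 times that of simulated unchanged arrays. Of the circRNA probes past 2-fold, 62.3% were higher in LM2 under the 75th percentile scaling, against 47.3% after quantile normalization, 43.4% after cyclic loess and 42.9% in the deposited normalized values. Normexp gave 285 higher and 211 lower, the deposited values 295 and 392, and cyclic loess 501 higher.

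The third comparison was between 1833 and the parental line. ASCRP3009212 was 20.1-fold higher in 1833, at a scaled intensity of 925 against 46.0, and ASCRP3003805 was 17.6-fold higher, at 895 against 51.0. On the log2 scale these were 4.33 and 4.13, against 3.30 and 3.26 under normexp. ASCRP3010112 was 20.7-fold lower, at 230 against 4760, and ASCRP3005803 was 16.5-fold lower, at 1589 against 26149. Among 12290 probes measured on both arrays, 589 were at least 2-fold higher and 647 at least 2-fold lower, together 10.1%. At 4-fold the counts were 64 and 64. By their bounds, 68 of 151 probes seen only in 1833 of this pair were at least 2-fold higher and 37 of 263 seen only in the parental line were at least 2-fold lower. The scaled detection floor of 1833 was 1.24 times that of the parental line, which favours larger bounds on the higher side, also for mRNAs. Of 54 measured mRNAs, 2 were at least 1.5-fold higher and 13 at least 1.5-fold lower. The higher ones were *ODC1* at 1.47 ± 0.23 and *LOX* at 0.86 ± 0.11. *RPAP3* differed by -1.65 ± 0.10, *ZAP70* by -1.47 ± 0.20 and *NOC3L* by -1.27 ± 0.11. *SPDL1* differed by -0.99 ± 0.05, *ATAD2*, encoding a bromodomain ATPase, by -0.82 ± 0.18 and *ACTB* by -0.71 ± 0.04. The exonuclease gene *EXO1* differed by -0.67 ± 0.06 and the RecQ helicase gene *WRN* by -0.61 ± 0.08. *GRM4* was at least 1.87-fold higher, and the chromatin gene *BAZ1A*, seen in the parental line alone, was at least 1.56-fold lower. The median of the 49 mRNAs measured on all 4 arrays was -0.17, at percentile 5.48 of the random circRNA lists. The SD of the circRNA differences was 0.65, 4.94 times that of simulated unchanged arrays. Normexp gave 232 higher and 296 lower circRNA probes and the deposited values 357 and 345, and under normexp 4 of the 15 mRNAs stayed past 1.5-fold, where *ODC1* differed by 0.30 and *LOX* by 0.36. In that setting *RPAP3* differed by -1.04, *ZAP70* by -0.57, *NOC3L* by -0.54, *ATAD2* by -0.32 and *EXO1* by -0.57.

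**Figure D1:**
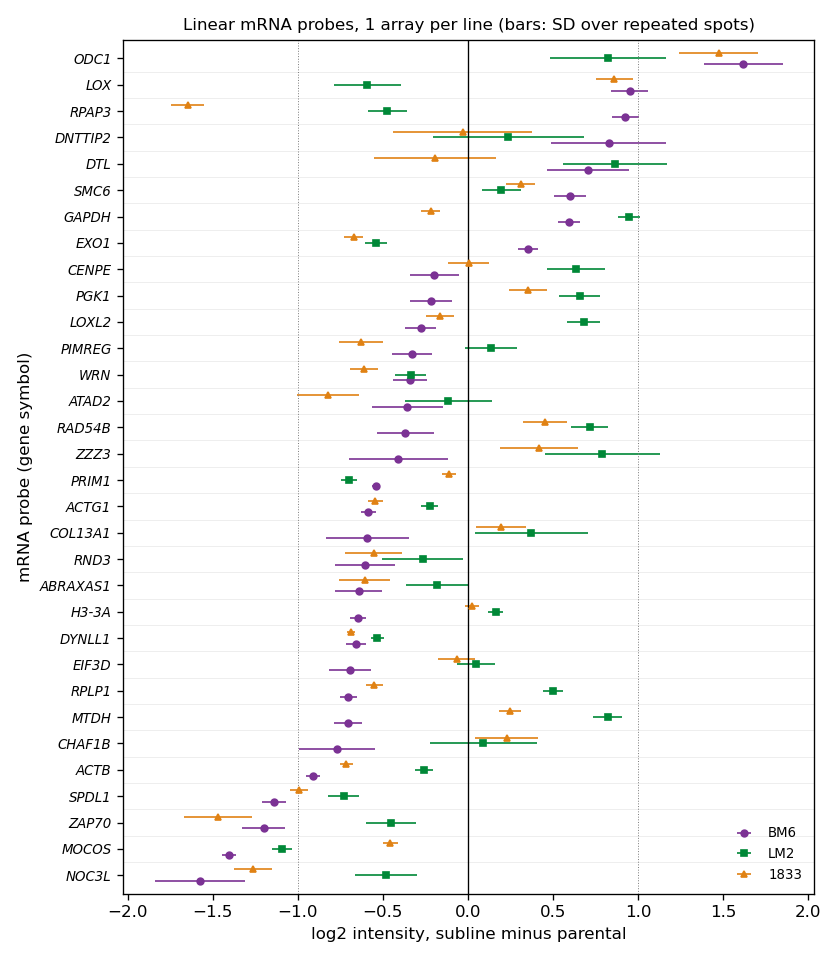
Log2 intensity of each subline minus the parental line (x axis) for 32 of the 33 linear mRNAs measured on all 4 arrays that were at least 1.5-fold apart in 1 or more sublines (y axis, gene symbols), under the 75th percentile scaling without adjustment for the LM2 median of 0.12. Points are 1 array per line, bars are the SD over repeated spots and dotted lines mark 2-fold. *ODC1* lies right of 0 in all 3 sublines, though in LM2 it could be measured only if higher. *RPAP3* is at 0.92 in BM6 and -1.65 in 1833.

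The gene lists fixed for host genes could be applied only to the linear mRNAs, and 6 of the 19 lists had a gene on that panel. None had 5 measured members, so no list was tested. Among extracellular matrix genes, *LOX* differed by the values above, *COL13A1*, a collagen gene, by -0.59 ± 0.24 in BM6 (-0.17 under normexp and -0.57 after cyclic loess), and *LOXL2*, a relative of *LOX*, by 0.56 ± 0.10 in LM2 relative to the circRNA median. On that basis *LOXL2* was at 0.52 after quantile normalization, 0.48 after cyclic loess and 0.40 under normexp. *COL13A1* was also the single measured member of the brain metastasis list and *LOXL2* that of the lung metastasis list. *SPP1* (osteopontin), the member of the bone metastasis list, was not well above background in any line. Of 4 measured cell cycle and DNA repair genes, *SMC6* was at least 1.5-fold higher in BM6 and *WRN* at least 1.5-fold lower in 1833, with *RAD54B* in LM2 as given above. The calls of *SMC6* and *WRN* ended under normexp, at 0.31 and -0.43, and that of *WRN* also after quantile normalization at -0.57 and cyclic loess at -0.58. No member of the fixed marker lists of epithelial, neural, immune and stromal cells was on the panel.

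The circRNAs common to the sublines were then examined. Of 11920 probes measured on all 4 arrays, 2662 were at least 2-fold from the parental line in 1 or more sublines and 1964 in exactly 1. In all 3 sublines, 85 probes were at least 2-fold higher and 79 at least 2-fold lower. These comparisons share the parental array, so each line was also set apart from the other 3. The parental line was at least 2-fold from each other line on 164 probes (1.38%), BM6 on 198 (1.66%), LM2 on 216 (1.81%) and 1833 on 215 (1.80%). Between BM6 and LM2, 199 probes were higher in both and 160 lower in both, where independent lists would share 36.9 and 21.3. For BM6 and 1833 the overlaps were 158 and 145 against 25.7 and 26.7, and for LM2 and 1833 they were 182 and 159 against 36.5 and 26.1. The log2 differences correlated at 0.46 for BM6 with LM2, 0.42 for BM6 with 1833 and 0.49 for LM2 with 1833, while simulated unchanged sublines against the shared parental array gave 0.50 for each pair. The covariances were 0.19, 0.17 and 0.21, against 0.0072 in the simulations, which hold spot noise alone. The shared parental array, whose own preparation cannot be separated with 1 array, may account for part or all of the excess over independent lists. For pairs that share no array, BM6 minus parental correlated at 0.044 with LM2 minus 1833, and LM2 minus parental at 0.048 with 1833 minus BM6. A difference common to all 3 sublines would cancel in LM2 minus 1833 and in 1833 minus BM6. These values therefore cannot tell whether the sublines share differences from the parental line.

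**Figure D2:**
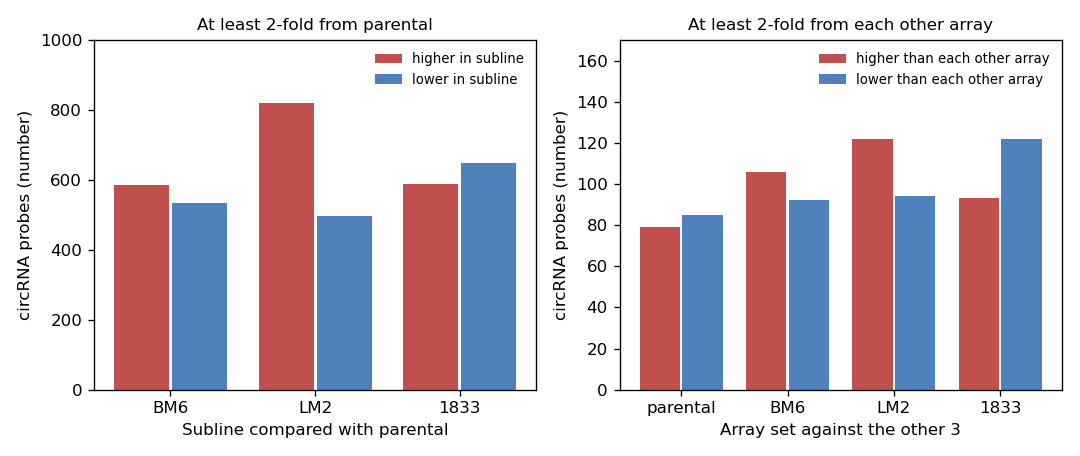
Number of circRNA probes (y axes) at least 2-fold higher (red) or lower (blue) in each subline than in the parental line (left), and number at least 2-fold from each of the other 3 arrays for each line (right). Each bar is a count from 1 array per line; LM2 has 821 higher and 497 lower probes on the left, and the parental line has 79 higher and 85 lower on the right.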

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

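The tests of LM2's scaling, of separate preparation and of digestion in BM6 were chosen after the result was seen; those of dim probes and of the array surface were chosen before it.

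Linear mRNAs moved in opposite directions in different sublines, and these differences between sublines were not tested, since each line has 1 array. *LOX* differed from the parental line by 0.95 in BM6 and 0.86 in 1833 but by -0.59 in LM2 on the log2 scale. Under normexp it was at 0.42, 0.36 and 0.33, and the last is 0.09 relative to the LM2 circRNA median of 0.24 in that setting, within the spot SD of 0.20 of the main value. *MTDH* differed by -0.70 in BM6 and 0.82 in LM2 (-0.43 and 0.74 under normexp, the latter 0.50 relative to the median). *RPAP3* differed by 0.92 in BM6 and -1.65 in 1833 (0.73 and -1.04 under normexp). Among circRNA probes, 15 were at least 2-fold apart from the parental line in opposite directions in BM6 and LM2, 11 in BM6 and 1833, and 7 in LM2 and 1833, again untested. Probes outside the comparisons also gave signal. All 15 of the designer's circRNA control probes were well above background on all 4 arrays. Of them, 3 were at least 2-fold higher than in the parental line in BM6, 2 in LM2 and 0 in 1833, and 0 were 2-fold lower in any. Among circRNA probes 585 of 12282 were higher in BM6, 821 of 12040 in LM2 and 589 of 12290 in 1833. A larger share of controls than of circRNA probes was thus higher in BM6 and LM2, although the controls are few. Of 60 negative control probes, 6 were well above background on all 4 arrays, and Negative009 differed by 1.49 ± 0.06 in BM6 and 1.39 ± 0.08 in LM2 (SD over repeated spots), while Negative051 differed by -1.23 ± 0.14 in BM6. Of these 6, 1 was at least 2-fold higher and 1 lower in BM6, where 9.10% of circRNA probes passed 2-fold. In LM2 1 was higher and 0 lower, and in 1833 0 passed 2-fold. What either kind of control probe targets is not given.

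In LM2, 62.3% of circRNA probes past 2-fold were higher. Among the brighter probes 45.6% were higher, so the excess was not seen there. The main scaling aligned the arrays at a percentile that lies among the brighter probes, which pulls their share toward even by construction. That share therefore cannot decide whether dim probes near background account for the imbalance. With each array centred on its median the share over all measured probes was 54.5%. Centring also pulls it toward even by construction, so scaling of a dim array stays open. The filter also favours higher probes, since the scaled floor of LM2 was 2.18 times that of the parental line. A probe between these floors in the parental line is counted only if higher in LM2. How much of the imbalance comes from this was not tested. A difference between the lines stays open too, as untested.

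Each of the 4 arrays stood apart from the others by a similar amount, on between 164 and 216 probes. A gradient over the array surface was argued against, since differences of adjacent spots correlated at 0.0047 at most. Separate culture, RNA preparation, digestion and labelling of each array could give correlations near 0.50 between sublines, and the highest was 0.49. Real differences between 4 lines of common origin would give the same value, so with 1 array per line these cannot be told apart.

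The mRNA panel lay lower than circRNA probes in BM6, where 36 of 49 mRNAs (73.5%) were below the circRNA median. The share was similar in 1833, at 33 (67.3%), and was 21 (42.9%) in LM2. More complete digestion of linear RNA in the BM6 preparation may be the cause, but separate differences of these mRNAs can give this share and cannot be told apart from it with 1 preparation per line. *ODC1*, *LOX* and *RPAP3* went the other way, at 1.62, 0.95 and 0.92.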

How the results depend on the processing

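The alternatives given here were planned, except that normexp used the median signal in place of the mean. The counts of mRNAs past 1.5-fold, and values relative to a circRNA median, were not part of the plan. The named differences, 52 of mRNAs and 12 of circRNA IDs, had the same sign under quantile normalization, median scaling and cyclic loess (64 of 64 each), and 63 of 64 under normexp, where *LOX* in LM2 turned from -0.59 to 0.33; the median LM2 circRNA difference was then 0.24, and *LOX* was 0.09 above it. The number of mRNAs that stayed past 1.5-fold in the same direction varied: of 22 in BM6, 19 after quantile normalization, 22 after median scaling, 19 after cyclic loess and 4 under normexp. Of 15 in LM2 these were 8, 14, 7 and 12, or 8, 12, 7 and 3 relative to the circRNA median of each setting, and of 15 in 1833 they were 14, 15, 14 and 4. In the deposited values, which hold no mRNA, 12 of 12 kept their sign. Counts under quantile normalization and median scaling stayed within 1.5 times the main counts in each comparison, and between 78.9% and 99.8% of the main calls were shared in the same direction. Cyclic loess gave 501 probes higher in LM2 and r = 0.960 between LM2 and 1833. Unless said otherwise the cause of a change was not tested. Normexp gave 243 higher and 231 lower in BM6, 285 and 211 in LM2, and 232 and 296 in 1833, and shared 36.4% to 42.3% of the main calls; its offset of 50 shrinks differences of dim probes by construction. Probes at least 2-fold from each other array then numbered 66 for the parental line, 72 for BM6, 77 for LM2 and 91 for 1833. Under normexp r was 0.970 for parental with BM6, 0.965 with LM2 and 0.966 with 1833, 0.963 for BM6 with LM2, 0.961 for BM6 with 1833 and 0.961 for LM2 with 1833. The deposited values gave 322 higher and 297 lower in BM6, 295 higher in LM2, and 357 and 345 in 1833. They set apart 86 probes for the parental line, 109 for BM6, 117 for LM2 and 129 for 1833, and r in the same order of pairs was 0.969, 0.964, 0.966, 0.963, 0.961 and 0.963. Without a filter on dim probes, 1460 were higher in LM2, the probes apart numbered 304 for the parental line, 301 for BM6 and 371 for LM2, and r was 0.971, 0.967, 0.969, 0.965, 0.966 and 0.966. With brighter probes alone, fewer were counted by construction: 255 higher and 239 lower in BM6, 209 and 249 in LM2, and 250 and 297 in 1833. The probes apart were then 65, 83, 82 and 95 for the parental line, BM6, LM2 and 1833, and r was 0.940, 0.932, 0.931, 0.932, 0.921 and 0.928. At 1.5-fold, which admits more by construction, 1693 were higher and 1691 lower in BM6, 2351 and 1497 in LM2, and 1753 and 2048 in 1833. Apart at that fold were 626 for the parental line, 927 for BM6, 1086 for LM2 and 1082 for 1833. The share of higher probes in LM2 ranged from 42.9% in the deposited values to 68.7% without the filter. The unfiltered share also counts probes near background, where the scaled floor of LM2 was 2.18 times that of the parental line. Negative control probes well above background on no array were also higher in LM2, such as Negative003 by 1.14 on the log2 scale. The 68.7% therefore cannot show a difference between the lines. Host gene lists, chromosomes and circRNA classes were not run, because probe IDs could not be tied to genes. No paired analysis was possible because each line had 1 array, which also left no replicate to leave out. Signal over background limits dim probes: spot noise was 0.23 on the log2 scale at the dimmest level and 0.032 at the brightest.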

Other observations

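The test given here was chosen before its result was seen. Several linear mRNAs lay on the same side of the parental array in all 3 sublines, and some are given as examples. Sharing that array makes such a pattern common by construction, and its frequency was not set against an expected share. *SPDL1*, of the mitotic spindle, differed by -1.14 ± 0.07 in BM6, -0.73 ± 0.09 in LM2 and -0.99 ± 0.05 in 1833 on the log2 scale, with errors as SD over repeated spots. *MOCOS* differed by -1.40 ± 0.04, -1.09 ± 0.06 and -0.46 ± 0.04. The dynein light chain gene *DYNLL1* differed by -0.66 ± 0.06, -0.53 ± 0.04 and -0.69 ± 0.02, and *ODC1* by 1.62 ± 0.23, 0.82 ± 0.34 and 1.47 ± 0.23. Under normexp *SPDL1* was at -0.75, -0.22 and -0.69 and *ODC1* at 0.42, 0.70 and 0.30, and that setting also used the median signal and an offset of 50. LM2 values here are not adjusted for its circRNA median of 0.12, or 0.24 under normexp. The scaled intensity of *ODC1* in the parental line was 10.6, dim enough that it could be measured in LM2 only if higher there. All 3 differences of a gene share the parental array, so an odd parental value would give the same picture.

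Among the circRNAs, ASCRP3005803 had scaled intensities of 26149 in the parental line, 6332 in BM6, 759 in LM2 and 1589 in 1833, and ASCRP3011481 had 20373, 4803, 683 and 1354. ASCRP3003805 was near 51.0 in the parental line and at 1755 in BM6, 1799 in LM2 and 895 in 1833. ASCRP3008906 was at 32.1 in the parental line and 31.9 in BM6 but at 2111 in LM2 and 530 in 1833. ASCRP3003814 was at 1375 in BM6 and 652 in 1833 and was not well above background in LM2.

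It was tested whether circRNA probes with neighbouring ID numbers may share an origin whose level differs between lines. The correlation of log2 differences between successive IDs was 0.017 in BM6, 0.032 in LM2 and 0.033 in 1833. In 1833 it lay above all 1000 shuffled orders, in LM2 1 shuffle was as high and in BM6 30 were. The correlation was far below the 0.1 set in advance, which argues against an order along successive IDs as a main source of the differences. It cannot detect a shared origin of probes whose IDs lie far apart, or of a few neighbours among many probes.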
